A study of Mus musculus with 24 samples.

How the data were processed

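Total RNA of mouse embryonic fibroblasts was amplified, labelled with Cy3 or Cy5 and hybridised to two-colour arrays, per the labels. The value table deposited by the authors gives the intensity of each probe in each channel on a linear scale. The channels of an array had nearly equal medians, so the values were taken to be normalized by the authors within arrays, while scanner, background correction and normalization method are not given in the sources used here. The submitters' processing notes name limma, without a version. The authors' comparison tables give a log2 difference, a mean log2 intensity and p-values or q-values, per the file headers. The mean log2 ratio of null over heterozygous channels over the 6 arrays of a background matched the log2 differences of the authors' deposited table within rounding, which settled scale and direction. The highest q-value in the authors' deposited SAM tables was 0.0937 and 0.151 for p53-null cells and 0.0661 and 0.135 for RasV12 cells, above the 1% and 5% in their names.

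Samples labelled as wild type for E4F1 are described by their genotype as heterozygous and are called so here. Of 137488 probes 5000 were random-sequence controls, whose 95th percentile per channel served as the background level. The other 132488 probes covered 44170 transcript accessions. Names came from the authors' deposited tables (4930 accessions), from RefSeq accessions in a reference table of mouse genes of assembly GRCm38.p6 (803) or from a symbol or synonym in that table (308). These gave 4704 named genes, 3666 of them through the authors' tables, and 38129 accessions stayed unnamed. Since most names exist because the authors called the probe, named genes are enriched for changed ones. List members called measured here are the named ones only, and the other members may be among the unnamed accessions. Counts adjusted over a list alone are therefore raised by the naming and do not describe whole pathways. Camera compares a list with the other named genes, while fry tests a list against no change. Of the authors' identifiers 127 were not in the reference and kept the authors' symbol, 122 accessions had a blank symbol, and 1 reporter of the authors' tables was not matched to the values used here. Coordinates are not given, because the build of the array is not given in the sources used here.

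Each probe's intensity was taken to log2 with a pseudocount of 0, and probes were averaged to 1 value per gene, or per accession where unnamed, which left 42833 features. The 2 dye-swapped arrays of a replicate pair were averaged, giving 6 null-minus-heterozygous differences. Whether swapped arrays used the same extracts is not stated, and they were counted as 1 replicate. Analysis used R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. The E4F1 effects, their mean and their difference were fitted with lmFit and eBayes on the 6 pair differences in 1 fit, and the RasV12 effect on the 12 replicate values in 4 groups without a block. P-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. Both members of a pair share their arrays, which is why the pair is a block. The deviations of pair members from their group means correlated at 0.701, 0.644 and 0.677 for the p53-null pairs A, B and C and at 0.236, -0.194 and 0.453 for the RasV12 pairs.

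A gene counted as not above background in a group when no channel of that group exceeded the background level with any of its probes, and its fold is then given as a bound. The bound sets the mean of the brighter group against the mean, over the replicates of the dimmer group, of the higher of the background level and the measured value. The near-identical copy Ndufs5-ps is reported as uncertain.

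Gene lists, 39 in number, were written down beforehand, and the 29 with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, under which 0 list calls remained in any comparison, and fry as the other. Overlap was tested with a one-sided Fisher's exact test. Genes to be named were set by a rule: E4f1, all reported E4F1 targets, per comparison the 8 largest rises and the 8 largest falls among called genes that moved the same way in all pairs (or whose groups did not overlap) and were not in the dimmest 25% of genes, per list up to 4 called members of largest change, or up to 2 of smallest p where none was called, and genes called in both backgrounds. Genes without a symbol were skipped, and some genes that the rule names are not reported here. The design, the naming rule, the lists and the alternatives were fixed before the data were examined, except those said to be chosen afterwards.

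The procedure was tested on simulated data with 200 changed genes among 42833. Simulated noise was normal, independent between genes and of equal spread in all groups. The real pairs had a median SD of 0.134 in p53-null and 0.222 in RasV12 cells. The false calls below therefore do not show how the fit behaves with unequal spreads or a replicate standing apart. For p53-null cells it called 11.9%, 62.7% and 93.9% of genes changed by 0.5, 1 and 2 log2 units, with 3 false calls. For RasV12 cells the shares were 5.97%, 58.2% and 89.4%, with 2 false calls. For both backgrounds together they were 34.3%, 82.1% and 98.5% with 7 false calls, for the difference 0%, 26.9% and 80.3% with 5, and for the RasV12 effect 1.49%, 50.7% and 97% with 3.

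Alternatives covered the block, each replicate left out, each dye orientation, single arrays with the pair as a random block, other normalizations, dim genes left out, the median over probes, a test per probe, a trended robust eBayes, a stricter threshold, a fold minimum, and each background fitted alone. Chosen after the data were seen were a test of genes above background alone and a test with the 6 arrays of a background taken as independent. The random-sequence probes were left out of all tests.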

Results

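The data came from mouse embryonic fibroblasts of 13.5-day embryos, profiled on 12 two-colour arrays that gave 24 channels. The cells lacked p53, and a part of them also carried an activated Ha-Ras oncogene (RasV12) delivered by retrovirus. Within each of these backgrounds, cells with 1 remaining E4f1 allele (called heterozygous) were set against cells with none (called null) 3 days after infection with a virus encoding Cre recombinase. E4F1 is a zinc-finger protein that acts as a transcription factor and as a ubiquitin ligase. The 4 groups held 3 biological replicates each, named A, B and C, and both members of a replicate pair were hybridised together on 2 arrays with exchanged dyes. The median intensity of a channel lay between 69.16 and 99.96. Between 40.3% and 46.86% of the probes in a channel were brighter than the 95th percentile of the random-sequence probes on the same array. For arrays of this kind, their number limits the precision. Heterozygous and null cells differed in genotype before Cre infection, by their labels, and so came from different embryos.

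E4f1 itself was measured first, as a check of the labels. In p53-null cells its log2 intensity was 6.94, 6.78 and 7.03 in the heterozygous replicates A, B and C and 6.18, 6.07 and 6.18 in the null replicates. In RasV12 cells it was 7.10, 7.12 and 7.14 in the heterozygous replicates and 6.06, 5.72 and 5.78 in the null replicates. The group means were 6.92 ± 0.13 and 6.14 ± 0.06 in p53-null cells and 7.12 ± 0.02 and 5.85 ± 0.18 in RasV12 cells (SD, n = 3). E4f1 fell in RasV12 cells by 1.27 on the log2 scale (SE 0.103, adjusted p = 0.00285) and was lower in all 3 pairs of either background. Its value in p53-null cells was -0.78 (SE 0.103, adjusted p = 0.307), and the call was made when that background was fitted alone (adjusted p = 0.000902). The brightest of its 6 probes gave -1.28 in p53-null and -1.99 in RasV12 cells, and exceeded background in 6 of 6 heterozygous channels of either background and in 2 and 3 of the 6 null channels. Which exons the probes match was not determined.

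The comparison of null with heterozygous p53-null cells asked which transcripts depend on E4F1 in immortal fibroblasts without an oncogene. Ndufs5, a subunit of respiratory complex I, fell by 2.22 on the log2 scale (SE 0.126, adjusted p = 0.0131, n = 3 pairs). Zfp945, a zinc-finger gene, fell by 1.28 (SE 0.102, adjusted p = 0.0348). Dnase1l2, an endonuclease gene in the neighbourhood of E4f1, rose by 1.23 (SE 0.0865, adjusted p = 0.0206). Ndufs5-ps, a near-identical copy of Ndufs5 whose probes may report the parent gene, gave -2.26 (adjusted p = 0.0206) and is uncertain. These were all of the genes past the threshold: 4 of 42833 by limma, 1 higher and 3 lower, with 1033 at an unadjusted p under 0.05.

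Genes reported as E4F1 targets were low as a group in the null p53-null cells. Of the 8 measured members 1 fell over all genes tested and 8 fell when adjusted over the list alone. The reports behind this list may rest on these samples, so the count is not independent evidence. All 8 had names through the authors' tables and 2 of the 10 listed had none, so an unchanged target could go uncounted. Dlat, the acetyltransferase subunit of pyruvate dehydrogenase, stood at -1.14 (adjusted p = 0.211). Senp8, a protease that removes NEDD8, stood at -1.02 and Taz, which remodels cardiolipin, at -0.94. The checkpoint kinase gene Chek1 stood at -1.06 (adjusted p = 1.00). Values for Dnajc19, a mitochondrial import co-chaperone, for Mpc1, a subunit of the mitochondrial pyruvate carrier, and for Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, were -0.80, -0.49 and -0.50. With the median over its probes Dnajc19 gave 0.17. The median of the list was -0.98 (camera adjusted p = 1.5e-19; adjusted p = 0.116 with an estimated correlation). Outside the list, Mrpl15 of the mitochondrial ribosome stood at -0.96 (adjusted p = 0.0746) and the recombination gene Rad52 at -0.96 (adjusted p = 0.15).

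Smaller shifts appeared in other lists of p53-null cells, none of which had a member past the threshold over all genes except the neighbourhood of E4f1. Contractile genes were lower in 13 of 13 members with a median of -0.35, and 3 fell when adjusted over the list alone (camera adjusted p = 5.02e-06; adjusted p = 0.116 with an estimated correlation). Among them Des, the intermediate filament desmin, stood at -0.82 and the matricellular factor Ccn2 at -0.85. NRF2 targets were higher in 11 of 13 members, with 2 that rose when adjusted over the list alone (camera adjusted p = 0.000469; adjusted p = 0.136 with an estimated correlation). The heme oxygenase Hmox1 stood at 0.51 and the quinone reductase Nqo1 at 0.52. Interferon-response genes were higher in 13 of 13 members, with 0 past the limma threshold in either adjustment (camera adjusted p = 0.00272; adjusted p = 0.598 with an estimated correlation). Their examples were the RNA-sensing enzyme Oas1a at 0.63 and the immunoproteasome subunit Psmb9 at 0.49. Fatty acid oxidation genes were higher in 5 of 5 members, with Eci1 at 0.45 and Eci2 at 0.27, and 1 rose when adjusted over the list alone (camera adjusted p = 0.00903; adjusted p = 0.344 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 9, with Cyp51 at -0.37 and Mvk at -0.27 and 0 past the limma threshold in either adjustment (camera adjusted p = 0.0454; adjusted p = 0.344 with an estimated correlation). The neighbourhood of E4f1 held 1 riser over all genes and 2 adjusted over the list alone among 11 genes (camera adjusted p = 0.0278; adjusted p = 0.378 with an estimated correlation).

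Calls in p53-null cells were sensitive to the model and to single pairs. The count was 197 with that background fitted alone, 79 higher and 118 lower, and 42 with single arrays and the pair as a random block. Without p53-null pair A, B or C limma called 0 genes (582, 580 and 522 at an unadjusted p under 0.05). Leaving out RasV12 pair A gave 29 calls, and leaving out RasV12 pair C gave 0 (1122 unadjusted). Trended robust eBayes gave 0 as well (755 unadjusted). List calls were lost without p53-null pair A for interferon response (adjusted p = 0.192), fatty acid oxidation (0.0602), cholesterol synthesis (0.106) and the neighbourhood of E4f1 (0.0874). The neighbourhood call was also lost without RasV12 pair A or B (0.115 and 0.075). The cholesterol call was lost as well without p53-null pair B or C (0.0702 and 0.052), without RasV12 pair A or B (0.0762 and 0.0596) and without the replicate block (0.111). With null RNA in Cy5 alone the fatty acid oxidation call was lost (0.17), and with null RNA in Cy3 alone those of cholesterol synthesis (0.277) and the neighbourhood (0.377). Fry lost those of interferon response (0.639), fatty acid oxidation (0.188) and the neighbourhood (0.0561).

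**Figure D1:**
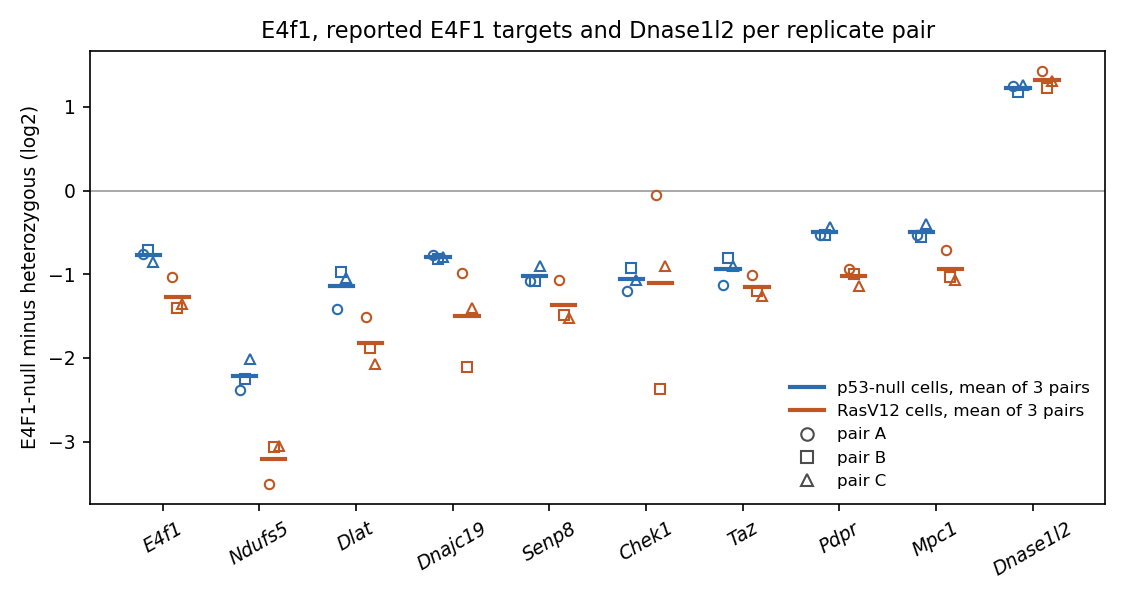
Null minus heterozygous log2 intensity (y axis) of E4f1, the 8 reported targets and Dnase1l2, with 1 point per replicate pair and a bar at the mean of 3 pairs in p53-null (blue) and RasV12 (orange) cells. Ndufs5 lies lowest, at means of -2.22 and -3.20, Dnase1l2 lies above 0 in all 6 pairs, and the RasV12 points of Chek1 range from -2.37 to -0.05.

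In RasV12 cells, where the comparison addressed the dependence of oncogene-transformed fibroblasts on E4F1, the reported targets fell. Ndufs5 fell by 3.20 (SE 0.126, adjusted p = 0.00047, n = 3 pairs), Dlat by 1.82 (adjusted p = 0.00203) and Dnajc19 by 1.5 (adjusted p = 0.0133). Dnajc19 rested on 1 bright probe of 3 (-4.14, against -0.16 and -0.20 for the dim ones), and with the median over its probes it gave -0.20. Senp8 fell by 1.36, Taz fell by 1.16, Pdpr fell by 1.02 and Mpc1 fell by 0.94, with adjusted p-values from 0.00327 to 0.00886. Chek1 gave -1.11 on average (adjusted p = 0.222), from pairs of -0.05, -2.37 and -0.91. In all, 7 of 8 measured members fell over all genes and 8 adjusted over the list alone, which is not independent evidence for the reason given above (median -1.26, camera adjusted p = 3.3e-06; adjusted p = 0.336 with an estimated correlation). Zfp945 fell by 1.49, Dnase1l2 rose by 1.32 and the uncertain Ndufs5-ps gave -3.17, as in p53-null cells.

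Limma called 786 of 42833 genes in RasV12 cells, 468 higher and 318 lower in null cells. Of these 325 changed at least 2-fold, 214 higher and 111 lower. Plac8, a small cysteine-rich protein, had the largest rise among the named genes, 4.92 (SE 0.870, adjusted p = 0.0427 by limma), with pairs of 6.17, 1.66 and 6.94. The SEs given for RasV12 cells pool the pairs of both backgrounds and are not the spread of the 3 RasV12 pairs alone. LOC68395 rose by 4.32 and the chemokine Cxcl12 by 4.26 (SE 0.208, adjusted p = 0.000508). The largest falls were those of the calcium-binding protein S100a4, -4.37 (SE 0.576, adjusted p = 0.0159), and of the positional homeobox gene Hoxd10, -4.21 (adjusted p = 0.00117). Gm2818 fell by 3.98, the carbonic anhydrase-related Car8 fell by 3.36 and neuritin, Nrn1, fell by 3.13. For Gm2818 heterozygous replicate A (8.04) stood below B and C (11.42 and 11.19). A further homeobox gene, Hoxa11, fell by 3.05 (SE 0.107, adjusted p = 0.000425). The natural killer receptor gene Klra4 rose by 3.29, although its heterozygous replicate A (9.47) stood above B and C (6.40 and 6.26).

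Genes of antigen processing, which formed no list of their own and were not tested as a set, were among those that rose in RasV12 cells. Psmb8 rose by 4.01 and Psmb9 by 3.63, both catalytic subunits of the immunoproteasome. The peptide transporter gene Tap1 rose by 3.14 and the class I heavy chains H2-Q7, H2-Q6 and H2-K1 by 3.70, 3.38 and 2.81. Of 13 measured interferon-response genes 6 rose and 1 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0584).

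Named matrix and contractile genes mostly rose in null RasV12 cells. The 18 named of 34 matrix genes and the 13 of 21 contractile genes all had names through the authors' tables. That raises the counts adjusted over each list alone. Of 18 matrix genes 8 rose and 1 fell, and 17 rose and 1 fell adjusted over the list alone (median 1.27, camera adjusted p = 0.00278; adjusted p = 0.42 with an estimated correlation). Decorin, Dcn, rose by 2.82, the gelatinase Mmp2 by 2.51 and tenascin C, Tnc, by 1.88, while the fibrillar collagen gene Col3a1 fell by 1.79. Heterozygous replicate A stood above B and C for Dcn (11.3 against 8.8 and 8.6) and Tnc (10.2 against 7.7 and 7.7). Of 13 contractile genes 6 rose, and 9 rose adjusted over the list alone (median 0.80, camera adjusted p = 0.0107; adjusted p = 0.336 with an estimated correlation). Tagln, which encodes the actin-binding protein transgelin, rose by 2.76 (SE 0.161, adjusted p = 0.00107), Ccn2 by 1.96, the myosin light chain gene Myl9 by 1.95 and smooth muscle actin, Acta2, by 1.87. Among 16 secreted inflammatory factors 4 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone. Beside Cxcl12 these included Igfbp7, which binds insulin-like growth factors and rose by 3.01, the alarmin Il33, which rose by 3.28, and the chemokine Cxcl5, which fell by 2.35 (camera adjusted p = 0.0584 for the list).

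Among mitochondrial lists, that of the ribosome passed in null RasV12 cells. Of its 78 genes 14 were named, 12 of them through the authors' tables, which raises the counts adjusted over the list alone. Of 14 mitochondrial ribosome genes 2 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone (median -0.50, camera adjusted p = 0.000238; adjusted p = 0.336 with an estimated correlation). Mrpl15 fell by 1.40 (adjusted p = 0.00117) and Mrpl54 fell by 0.53, while Mrpl23 rose by 0.95. Of 13 import and chaperone genes 4 fell and 0 rose by limma, namely Dnajc19, Dnajc15 (-1.05), the import pore subunit Timm23 (-0.95) and the nucleotide exchange factor Grpel1 (-0.75), but 5 of the 13 were higher and the list as a whole did not pass (camera adjusted p = 0.15). Of 6 mitochondrial tRNA synthetase and translation genes 1 fell, and that list did not pass either (camera adjusted p = 0.0584). Complex I held 2 members that fell among 11, Ndufs5 and Ndufa13 (-0.62), while 7 of the 11 were higher, and 5 rose and 4 fell adjusted over the list alone (median 0.25). Ndufa13 lay near background, which it exceeded in 5 of 6 heterozygous and 1 of 6 null RasV12 channels. Complexes II to V held 1 that fell among 9, Uqcr10 (-0.51), and 1 rose and 6 fell adjusted over the list alone. Neither respiratory list passed as a whole (camera adjusted p = 0.728 and 0.0584).

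Fatty acid synthesis genes were the metabolic list that rose. Of 7 fatty acid synthesis genes 2 rose, the acetyl-CoA synthetase Acss2 by 1.48 and malic enzyme, Me1, by 0.90, and 7 rose adjusted over the list alone (median 0.54, camera adjusted p = 0.0326; adjusted p = 0.336 with an estimated correlation). Cyp51 rose by 0.99 and Mvd by 0.76 among 9 cholesterol synthesis genes (camera adjusted p = 0.216 for the list). Hexokinase 2, Hk2, rose by 0.77 as the only member past the threshold over all genes among 8 glycolysis genes, of which 8 rose adjusted over the list alone (camera adjusted p = 0.0584). The pyruvate dehydrogenase kinase Pdk4 rose by 0.79, and the hypoxia-induced genes Adm and Ndrg1 rose by 2.65 and 1.74. Of 13 NRF2 targets 2 rose and 1 fell, and 7 rose and 4 fell adjusted over the list alone (median 0.48, camera adjusted p = 0.728). The faller was Nqo1, by 2.12 (SE 0.134, adjusted p = 0.00117). Of 8 p53-induced genes, in cells without p53, the kinase inhibitor gene Cdkn1a fell by 1.16 and Plk2 rose by 1.08. Rad52 fell by 1.39, Myc rose by 1.22 and the ribosomal gene Rps4x by 0.77, a value that ranged from 0.28 to 1.26 across the alternatives. Syngr3, a synaptic vesicle gene near E4f1, rose by 1.21. Markers of other cell types gave 1 riser each among 4 skeletal muscle, 5 neural, 4 epithelial and 3 adipocyte markers, while 0 passed by limma among 2 endothelial markers and 1 macrophage marker.

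The RasV12 count depended on the model and on which pairs were in the fit. Its p-values rest on a spread pooled with the p53-null pairs, whose median SD was 0.134 against 0.222 for RasV12 pairs. With RasV12 cells fitted alone limma called 0 genes (3243 at an unadjusted p under 0.05), and with trended robust eBayes 0 (5604 unadjusted), so none of the genes named for RasV12 cells passed under either. Heterozygous RasV12 replicate A stood apart, with 3552 genes over 1 log2 unit from the mean of B and C, and without pair A the count was 2476. Without RasV12 pair B it was 1293, and without p53-null pair A, B or C it was 238, 166 or 162. Without the replicate block it was 309, of which 282 were among the 786. Of the 61 called genes named here for RasV12 cells, 39 passed without the block, 35, 32 and 31 passed without p53-null pair A, B or C, and 61, 58 and 46 passed without RasV12 pair A, B or C.

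**Figure D2:**
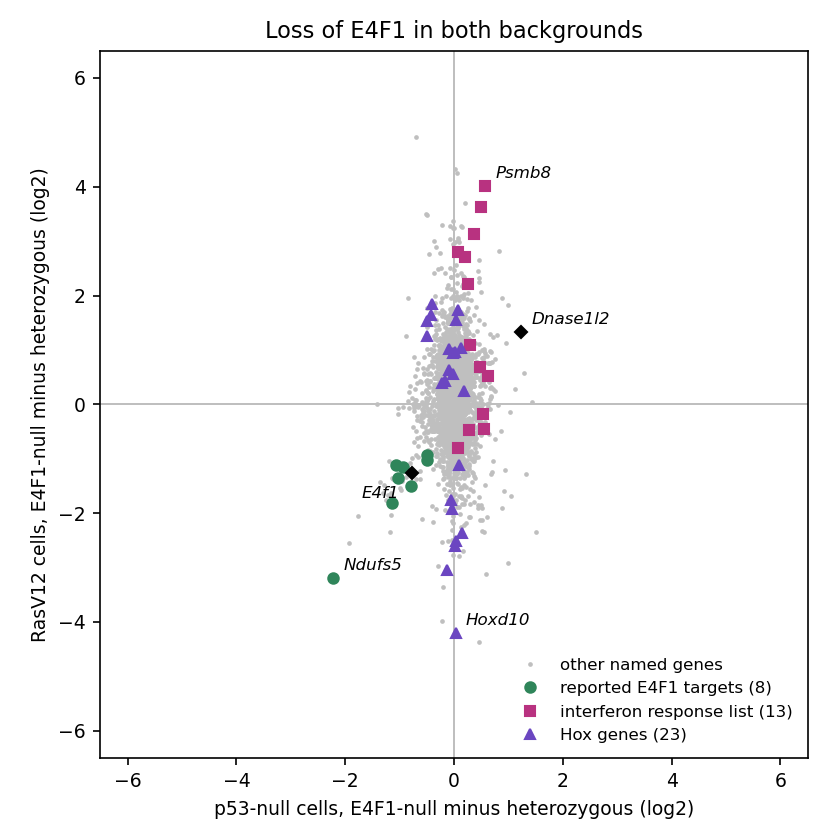
Null minus heterozygous log2 difference in p53-null cells (x axis) against that in RasV12 cells (y axis), 1 point per named gene, with the 8 reported E4F1 targets, 13 interferon-response genes, 23 Hox genes, E4f1 and Dnase1l2 marked. The targets lie below 0 on both axes, whereas Psmb8 (4.01) and Hoxd10 (-4.21) lie far from 0 on the RasV12 axis alone.

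Averaged over both backgrounds and 6 pairs, 139 genes passed, 82 higher and 57 lower. Ndufs5 fell by 2.71 (SE 0.0888, adjusted p = 0.000257), and the uncertain Ndufs5-ps gave -2.71. Mrfap1 fell by 2.24 and the proteasome subunit gene Psmb6 by 1.77 (SE 0.084, adjusted p = 0.000801). A930005H10Rik fell by 1.60, and Elp3, the catalytic subunit of Elongator, fell by 1.5. E4f1 fell by 1.02 (SE 0.0726, adjusted p = 0.00346). Among the reported targets Dlat fell by 1.48, Senp8 fell by 1.19, Dnajc19 fell by 1.15 (-0.01 with the median over its probes), Taz fell by 1.05, Pdpr fell by 0.76 and Mpc1 fell by 0.72, and Chek1 gave -1.08 (adjusted p = 0.214). The list had 7 members that fell among 8, and 8 adjusted over the list alone, again not independent evidence (median -1.12, camera adjusted p = 3.25e-09; adjusted p = 0.425 with an estimated correlation). Mrpl15 fell by 1.18 and Rad52 fell by 1.17. Of 14 mitochondrial ribosome genes 1 fell, and 9 fell and 1 rose adjusted over the list alone (median -0.24, camera adjusted p = 0.000621; adjusted p = 0.425 with an estimated correlation).

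The rises named over both backgrounds came mainly from RasV12 cells, apart from that of Dnase1l2. Psmb8 rose by 2.29, Cxcl12 by 2.16, Psmb9 by 2.06, Tap1 by 1.75, H2-D1 by 1.46 and Tap2 by 1.40, while in p53-null cells they stood at 0.57, 0.06, 0.49, 0.36, 0.20 and 0.46, none called there. Of 13 interferon-response genes 6 rose, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.501 with an estimated correlation), a call lost without RasV12 pair B (adjusted p = 0.151). Dnase1l2 rose by 1.27 (SE 0.0612, adjusted p = 0.000801). The endophilin gene Sh3gl3 rose by 1.08 and LOC547349 by 1.06, against 0.17 and 0.14 in p53-null cells. Igfbp7 rose by 1.32 and Tagln by 1.15, although in p53-null cells Igfbp7 stood at -0.36 and Tagln at -0.46, called lower with that background fitted alone (adjusted p = 0.0428). Of 18 matrix genes 3 rose, among them Mmp2 by 1.13 (-0.24 in p53-null cells), and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.425 with an estimated correlation). The count without the replicate block was 84, of which 65 were among the 139, and with trended robust eBayes limma called 0 (2407 unadjusted). Without p53-null pair A, B or C the count was 19, 17 or 9, and without RasV12 pair A or B it was 970 or 367. Of the 27 called genes named here for both backgrounds 10, 10 and 5 passed without p53-null pair A, B or C, and 27, 27 and 24 passed without RasV12 pair A, B or C.

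A few genes were called in both backgrounds. In the downward direction 3 genes were shared, Ndufs5, Zfp945 and Ndufs5-ps, the last of which may be Ndufs5 counted again, against 0.0223 for independent lists (one-sided Fisher's exact test, p = 4.05e-07). In the upward direction Dnase1l2 was the 1 shared gene, against 0.0109 (one-sided Fisher's exact test, p = 0.0109). Both lists came from 1 fit with a spread shared between backgrounds, which the expectation for independent lists leaves out of account. Without any p53-null pair, or without RasV12 pair C, the p53-null list was empty and nothing was shared.

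The authors' deposited table of limma results held 493 reporters for p53-null cells, 162 higher and 331 lower in null cells, and 4703 for RasV12 cells, 2869 higher and 1834 lower. Of those reporters 37 were shared upward, against 3.51 for independent lists, and 152 downward, against 4.58. A test of each probe that treated the 6 arrays of a background as independent, chosen after the data were seen, called 322 and 4564 probes. Of these, 320 and 4480 were in the authors' deposited table. The authors' deposited tables of SAM results held 503 and 949 reporters for p53-null cells, and 4291 and 8601 for RasV12 cells, at the levels of 1% and 5% in their names.

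The difference between backgrounds was tested directly, as the RasV12 effect minus the p53-null effect. Limma called 105 genes, 72 with a higher and 33 with a lower value in RasV12 cells. LOC68395 differed by 4.32 and Cxcl12 by 4.20 (SE 0.294, adjusted p = 0.007). H2-Q7 differed by 3.51, Psmb8 by 3.44, H2-Q6 by 3.39, Igfbp7 by 3.37 (SE 0.192, adjusted p = 0.00623) and Il33 by 3.35. Il33 lay near background in p53-null cells, which it exceeded in 3 of 6 channels of either group. Ucp1, the uncoupling protein of brown fat, was called too, but no p53-null channel exceeded background for it, so that its effect there was not measured and no exact difference can be given. In the other direction Hoxd10 differed by -4.24, Nrn1 by -3.72, Hoxa11 by -2.92, Nqo1 by -2.64, the calmodulin-like Calml4 by -2.52, Hoxd12 by -2.50, the LIM-domain gene Crip2 by -2.40 and the glucuronosyltransferase Ugt1a10 by -2.35. Hoxd12 exceeded background in 1 of 6 null RasV12 channels. E4f1 itself gave -0.49 (adjusted p = 0.338) and Ndufs5 gave -0.98 (adjusted p = 0.118), neither past the threshold.

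Gene lists also differed between backgrounds. Contractile genes were 13 of 13 on the positive side, with 3 past the threshold over all genes and 12 adjusted over the list alone (median 1.13, camera adjusted p = 0.000163; adjusted p = 0.345 with an estimated correlation), among them Tagln at 3.21, Ccn2 at 2.80 and Acta2 at 2.23. Matrix genes had 2 past the threshold, Mmp2 at 2.74 and the proteoglycan gene Bgn at 1.64, and 10 positive and 1 negative adjusted over the list alone (camera adjusted p = 0.00933; adjusted p = 0.598 with an estimated correlation). Inflammatory factors had 4 of 16 past it, including Cxcl12, Igfbp7 and Il33, and 7 positive and 1 negative adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.475 with an estimated correlation). Interferon-response genes had 6 of 13 past it, among them Psmb9 at 3.14, Tap1 at 2.77 and H2-K1 at 2.74, and 6 positive and 1 negative adjusted over the list alone, but the list did not pass (camera adjusted p = 0.126). Fatty acid synthesis genes had 0 of 7 past it by limma and 7 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.406 with an estimated correlation). Mitochondrial ribosome genes had 0 of 14, with 9 negative and 1 positive adjusted over the list alone (camera adjusted p = 0.000977; adjusted p = 0.406 with an estimated correlation). Mitochondrial tRNA synthetase and translation genes had 0 of 6, with 4 negative adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.475 with an estimated correlation). The reported targets had 0 of 8, with 4 negative adjusted over the list alone, not independent evidence (median -0.48, camera adjusted p = 0.00857; adjusted p = 0.508 with an estimated correlation).

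Calls of the difference also depended on single pairs. Without p53-null pair A, B or C limma called 2, 0 and 0 genes (2489, 2451 and 2284 unadjusted), and without RasV12 pair A or B it called 915 and 385. Without RasV12 pair A, B or C, 24, 24 and 21 of the 24 called genes named here for the difference passed. Without RasV12 pair B the calls of the targets (adjusted p = 0.0604), matrix (0.0604) and inflammatory (0.0997) lists were lost, and without pair C that of the inflammatory list (0.0618). The call of mitochondrial tRNA synthetases was lost without p53-null pair B or C (0.0946 and 0.0565) and without RasV12 pair A or B (0.0956 and 0.0604). Without the replicate block the count was 56, of which 42 were among the 105, and the tRNA synthetase call was lost (0.0991), as it was with null RNA in Cy3 alone (0.0767). With trended robust eBayes limma called 0 genes (3484 unadjusted).

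**Figure D3:**
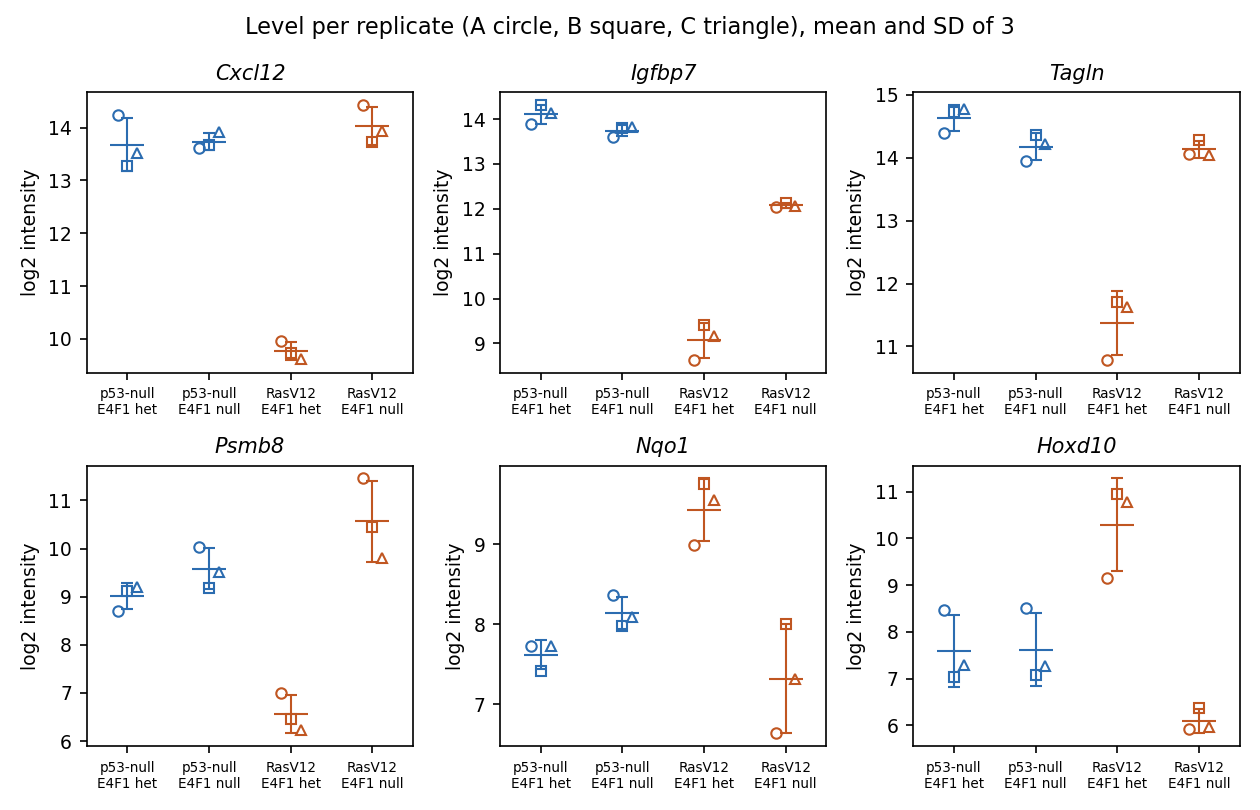
Level of Cxcl12, Igfbp7, Tagln, Psmb8, Nqo1 and Hoxd10 (y axis, log2 intensity) in the 4 groups, with 1 point per replicate and the mean ± SD of 3 replicates. Cxcl12 stood at 9.77 in heterozygous RasV12 cells and between 13.68 and 14.03 in the other 3 groups.

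RasV12 was compared with p53-null cells in the heterozygous state, to describe the transformed cells in which loss of E4F1 was then measured. Known RAS outputs rose. The ETS factor Etv1 rose by 3.20 (SE 0.262, adjusted p = 2.35e-05), the AP-1 subunit gene Fosl1 by 1.97, the chromatin protein gene Hmga1 by 1.73 and Etv4 by 1.23. Of 14 RAS and MAPK output genes 5 rose, and 7 rose adjusted over the list alone (median 0.97, camera adjusted p = 1.65e-05; adjusted p = 0.763 with an estimated correlation). The largest rises were those of the secreted neuronal pentraxin Nptx1, 5.34 (SE 0.492, adjusted p = 5.32e-05), of Gchfr, which regulates tetrahydrobiopterin synthesis, 5.05, and of the zinc transporter gene Slc30a4, 4.80. Uridine phosphorylase, Upp1, rose by 4.46, Nrn1 by 4.42, the protease inhibitor Cst6 by 4.31, stanniocalcin, Stc1, by 3.87 and the heparan sulphotransferase Hs3st1 by 3.71.

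Matrix and contractile genes fell with RasV12. Postn, the matricellular protein periostin, fell by 5.47 (SE 0.465, adjusted p = 2.93e-05). Prss23 fell by 5.18, Lrrc15 fell by 5.12, Ccn5 fell by 5.07 and Igfbp7 fell by 5.04 (SE 0.188, adjusted p = 2.37e-08). Ccn5 exceeded background in 2 of 6 heterozygous RasV12 channels. Thrombospondin, Thbs1, fell by 4.40, the collagen gene Col1a1 fell by 3.24 and Mmp2 fell by 2.85. Of 18 matrix genes 12 fell, and 16 fell adjusted over the list alone (median -1.65, camera adjusted p = 1.04e-08; adjusted p = 0.321 with an estimated correlation). Of 13 contractile genes 12 fell, and 12 adjusted over the list alone (median -1.60, camera adjusted p = 1.53e-09; adjusted p = 0.0585 with an estimated correlation). Smooth muscle actins Actg2 and Acta2 fell by 3.60 and by 3.36 on the log2 scale, skeletal actin, Acta1, fell by 4.63, Tagln fell by 3.26 and Myl9 fell by 3.12. The value of Actg2 ranged from -6.37 to -3.21 across the alternatives. Plac8 fell by 4.59 (SE 1.09, adjusted p = 0.029). Tcfl5 was not above background in RasV12 cells and was at least 11.9-fold lower there (adjusted p = 1.19e-06).

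Inflammatory factors were mostly lower with RasV12, 12 of 16 members. Of these 16 members 6 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (median -1.33, camera adjusted p = 0.027; adjusted p = 0.763 with an estimated correlation). Cxcl12 fell by 3.90 and Igfbp5 fell by 3.62, while Il33, above background in 3 of 6 heterozygous p53-null channels, rose by 3.17. That call was lost without p53-null replicate B (adjusted p = 0.0597) or RasV12 replicate B (0.0715). Of 13 interferon-response genes 3 fell, Psmb8 by 2.45 on the log2 scale among them, and 5 fell adjusted over the list alone (camera adjusted p = 0.145). The class I light chain gene B2m fell by 1.00, a value of -1.84 with Cy3 and of -0.16, no longer past the threshold, with Cy5 channels alone, and Oas1a, not above background in RasV12 cells, was at least 4.93-fold lower. Of 9 cholesterol synthesis genes 3 fell, including Nsdhl, which fell by 1.08 (camera adjusted p = 0.0919 for the list). Nqo1 rose by 1.82, Cdkn1a rose by 1.21, Plk2 fell by 1.20 and Mpc1 fell by 0.81. E4f1 gave 0.20 (adjusted p = 0.439). Among markers of other cell types 2 of 4 skeletal muscle and 1 of 2 endothelial markers fell, 1 of 5 neural and 1 of 4 epithelial markers rose, 1 of 3 adipocyte markers rose and 1 fell, and 0 of 1 macrophage marker passed by limma.

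In total 2100 genes passed, 512 higher and 1588 lower with RasV12 (24.4% higher), and the median of all genes was -0.14. This comparison crosses arrays and so rests on the scale of the deposited values. With quantile normalization the median was 0.01 and the split was 1166 higher and 1417 lower (45.1% higher), and with each channel centred on its median the split was 1254 and 1067 (54% higher). Relative to the median, 9 matrix and 11 contractile genes still passed downward and 6 RAS output genes upward. The count was 1308, 1263 or 973 without p53-null replicate A, B or C and 4673, 1265 or 1142 without RasV12 replicate A, B or C. Of the 38 called genes named for this comparison, 35 to 38 passed with any 1 replicate left out.

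**Figure D4:**
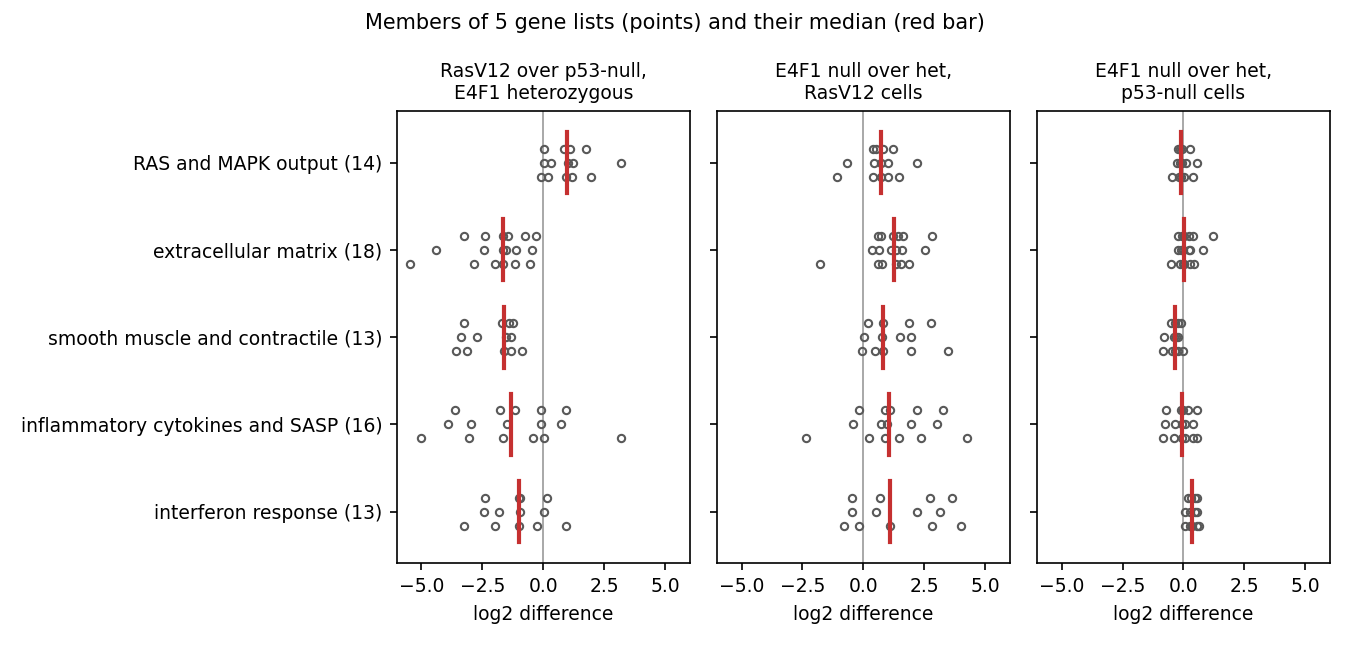
Log2 difference (x axis) of the measured members of 5 gene lists (points) and the median of each list (red bar), for RasV12 over p53-null cells in the heterozygous state and for null over heterozygous cells in each background. The matrix list lies at -1.65 with RasV12 and at 1.27 in null RasV12 cells.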

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

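The explanations in this part, and the values set against them, were chosen after the results were seen. The fits without a replicate pair and of each background alone were planned. So were the test of the difference between backgrounds and its splits. The test of the difference, made in 1 limma fit of all 6 pairs, singled out results whose E4F1 effect differed between RasV12 and p53-null cells. It called 105 genes. The genes named among them differed by 4.32 (LOC68395), 4.20 (Cxcl12), 3.51 (H2-Q7), 3.44 (Psmb8), 3.39 (H2-Q6), 3.37 (Igfbp7), 3.35 (Il33) and 3.25 (Ucp1) log2 units in the positive direction, where Ucp1 was not above background in p53-null cells and its value is no exact difference. In the negative direction they differed by -4.24 (Hoxd10), -3.72 (Nrn1), -2.92 (Hoxa11), -2.64 (Nqo1), -2.52 (Calml4), -2.50 (Hoxd12), -2.40 (Crip2) and -2.35 (Ugt1a10). Il33 in p53-null cells and Hoxd12 in null RasV12 cells lay near background, as given above. Among gene lists the adjusted p of the difference was 0.00857 for reported E4F1 targets, 0.000977 for the mitochondrial ribosome, 0.0202 for inflammatory factors, 0.0117 for fatty acid synthesis, 0.00933 for the matrix, 0.000163 for contractile genes and 0.046 for mitochondrial tRNA synthetases, each by camera with the preset correlation. With an estimated correlation 0 lists passed, and the smallest adjusted p by camera was 0.345. The 9 other splits of the 6 pairs into 3 and 3 called at most 0 genes against 105, and with 1 of 10 splits as the smallest share the splits are too few for a share under 0.05.

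Of 23 measured Hox genes 4 rose and 6 fell in RasV12 cells, where several antigen-presentation genes rose, and none of these was called in p53-null cells in the joint fit, while p53-null cells fitted alone gave calls for Hoxb8 (-0.505) and Hoxb9 (-0.502), opposite to RasV12 cells (1.262 and 1.539), and for H2-DMa (0.459). All 23 Hox genes together had a median absolute change of 1.539 in RasV12 cells, above all of 10000 random lists matched on level and naming (95% range 0.439 to 0.732), and of 0.094 in p53-null cells (range 0.061 to 0.176). A different positional origin of heterozygous and null RasV12 cells in the embryo stays open, since these genes drew attention to the pattern and cannot decide it, and genotype and embryo cannot be told apart in this design. Replicate A was not needed for the calls: without it 2476 genes were called, 61 of the 61 called genes named for RasV12 cells among them. That fit kept the p53-null spread, and heterozygous RasV12 replicates B and C correlated at 0.9955, against 0.9584 for A with B. The higher count therefore cannot decide whether differences between replicates contributed to the pattern. Weaker RAS output in null cells stays open, as does an effect of E4F1 itself: the RAS and MAPK output list had a median of 0.715 there, with 2 members that rose, and 9 that rose and 2 that fell adjusted over the list alone, which goes against it, but the list did not pass (camera adjusted p = 0.225) and Etv1 stood at -1.09 (adjusted p = 0.102).

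Dnase1l2 rose in both backgrounds. A rise of the whole region around E4f1 by as much is excluded, because the 10 other measured genes of the neighbourhood had a median of 0.162, from -0.424 to 0.589. A smaller rise of the region stays open: with Dnase1l2 9 of 11 genes were higher over both backgrounds and 6 rose adjusted over the list alone, Syngr3 rose in RasV12 cells (1.21), and the list did not pass over both backgrounds (camera adjusted p = 0.141). A change in cis from the deleted E4f1 allele may account for the rise of 1.275, and it cannot be told apart from loss of the protein because every null sample carries the deletion.

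Fewer genes were called in p53-null than in RasV12 cells in the joint fit. The fit shares 1 spread between backgrounds, and the median SD between pairs was 0.134 in p53-null and 0.222 in RasV12 cells. Fitted alone, p53-null cells gave 197 calls and RasV12 cells 0 by limma (3243 at an unadjusted p under 0.05). That turns the order and goes with the wider RasV12 spread limiting the joint count in p53-null cells. The narrower p53-null spread likewise entered the SEs and p-values of the 786 RasV12 calls. The p53-null change of E4f1 was 0.613 of its RasV12 change. In null cells E4f1 lay near background, which it exceeded in 2 of 6 p53-null and 4 of 6 RasV12 channels. The size of either fall, and so this ratio, is therefore uncertain. The 786 RasV12 calls had a median ratio of 0.003 (95% interval -0.007 to 0.019, with genes taken as independent). That argues against a smaller fall of E4f1 scaling all of these calls alike. They were chosen by their RasV12 change, and how many of them depend on E4F1 is not known. The 8 reported targets had a median ratio of 0.66 (lowest 0.488, highest 0.958), so such scaling stays open for them.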

How the results depend on the processing

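Tests of genes above background alone and of 6 arrays as independent were chosen after the data were seen. The cause of the moved counts was not tested, except where fewer samples, another threshold or more tests show it. Counts are of genes, for tests of probes as well. For p53-null cells (4 calls) single arrays with the pair as a random block gave 42, trended robust eBayes 0 (755 unadjusted), adjusted p 0.01 0 (1033 unadjusted), the background alone 197, genes above background 2, a test per probe 12, independent arrays 145, and leaving out a pair 0 to 29. For RasV12 cells (786) the values were 309 without the replicate block, 3040 with single arrays, 0 with trended robust eBayes (5604 unadjusted), 171 at 0.01, 0 with the background alone (3243 unadjusted), 1282 per probe, 1853 with independent arrays and 162 to 2476 with a pair left out. For both backgrounds (139) they were 84 without the replicate block, 251 with null RNA in Cy5, 388 with null RNA in Cy3, 1084 with single arrays, 0 with trended robust eBayes (2407 unadjusted), 43 at 0.01, 325 per probe and 9 to 970. For the difference (105) they were 56 without the replicate block, 1020 with single arrays, 0 with trended robust eBayes (3484 unadjusted), 20 at 0.01, 241 per probe and 0 to 915. For the RasV12 effect (2100) they were 1164 with Cy5 and 4398 with Cy3 channels alone, 903 at 0.01 and 973 to 4673 with a replicate left out. The replicate letter as a block gave 2675, but the labels do not pair the backgrounds by letter: p53-null replicates A and C deviated most like RasV12 replicates A and C (r = 0.048 and 0.131 across genes), and B most like A (0.072, against -0.083 with B). List calls in p53-null cells went from 7 to 0 with an estimated correlation and 4 with fry, and to 3 to 8 with a pair left out. In RasV12 cells they went from 5 to 9 without the replicate block, 11 with null RNA in Cy5, 0 with an estimated correlation, 19 with fry, and 5 to 9. Over both backgrounds they went from 4 to 0, 20 with fry and 3 to 8, for the difference from 7 to 0, 12 with fry and 3 to 8, and for the RasV12 effect from 4 to 0 with an estimated correlation. The overlap of 4 genes was 189 reporters in the authors' deposited limma table and 175 and 272 in their SAM tables, and adjusted p 0.01 gave no value, since no p53-null gene passed. Among the named genes called in a comparison, 0 reversed under any alternative run by limma. For the RasV12 effect 32 of 38 passed under all alternatives. For the E4F1 effects 0 of 4 did so in p53-null cells, 0 of 61 in RasV12 cells and 0 of 27 over both backgrounds, and for the difference 0 of 24. The reversals were in genes without a call: Dnajc19 in p53-null cells was 0.17 with the median over its probes, of which 1 is bright, and E4f1 gave -0.086 for the RasV12 effect with Cy3 channels alone. Without the replicate block 6 of the 7 list calls in p53-null cells were kept, 4 of 4 over both backgrounds among 5, and 6 of 7 for the difference among 9. Dye-swapped arrays correlated at 0.119, 0.066 and 0.014 in p53-null pairs over all genes and at 0.343, 0.232 and 0.17 over the 18219 above background, and in RasV12 pairs at 0.796, 0.781 and 0.592 and at 0.893, 0.928 and 0.795.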

Other observations

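The tests of splits in this part were planned, and so was the fit of p53-null cells alone, while the genes named in this part were chosen after their values were seen. Fitted alone, p53-null cells lacking E4F1 gave 118 lower and 79 higher genes, and the 8 measured reported targets were among the lower ones. All 8 had names through the authors' tables and 2 of the 10 listed had none, so an unchanged target could go uncounted. Dnajc19, 1 of the 8, gave 0.17 with the median over its probes. Of the 118 lower genes 78 were also lower in RasV12 cells and 30 were called there in the joint fit, against 0.876 for independent lists. Of the 79 higher genes 51 were also higher and 8 were called there, against 0.863. The joint fit shares its spread with these same p53-null pairs, so the lists were not independent and these expectations leave that out of account. Mrfap1 fell by 1.94 (adjusted p = 8.92e-07) and Fam229b fell by 1.77 (adjusted p = 7.49e-06). Hax1, a mitochondrial anti-apoptotic protein, fell by 1.21 and Crls1, the cardiolipin synthase, fell by 1.19, each with an adjusted p of 3.85e-05. In RasV12 cells these genes stood at -2.55 (Mrfap1), -2.06 (Fam229b), -1.67 (Hax1) and -1.04 (Crls1). Penk, which encodes enkephalins, rose by 1.51 in p53-null cells fitted alone and stood at -2.35 in RasV12 cells, while Lum, a matrix proteoglycan, rose by 1.20 and stood at 1.32. The glutathione transferases Gsta4 and Mgst1 rose by 1.00 and 0.88 in p53-null cells, against 1.82 and -1.91 in RasV12 cells.

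In the null state RasV12 moved most genes the same way as in the heterozygous state. Of the 2100 genes called in heterozygous cells, 2016 had the same direction in null cells, 1596 had a smaller change there, and the median ratio was 0.749, where part of a smaller value follows from choosing genes by their heterozygous change. The list medians of the RasV12 effect were -1.65 and -0.78 for the matrix, -1.60 and -0.42 for contractile genes, and 0.97 and 1.82 for RAS and MAPK output, in heterozygous and null cells. They were -1.33 and 0.12 for inflammatory factors, -0.99 and 0.03 for interferon response, and -0.68 and -0.05 for cholesterol synthesis. Of the 318 genes that fell in null RasV12 cells 157 were lower in null p53-null cells, and of the 468 that rose 246 were higher.

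Among Hox genes in RasV12 cells 4 rose, Hoxb6 (1.84), Hoxb7 (1.65), Hoxb9 (1.54) and Hoxb8 (1.26), and 6 fell, among them Hoxa10 (-2.61), Hoxa9 (-2.51) and Hoxd8 (-1.12). The difference between backgrounds was called for 7 Hox genes. Xist was at 5.89 in both members of p53-null pair A and between 7.84 and 8.32 in pairs B and C.

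For single probes, of 44154 accessions with 3 probes 3 in p53-null and 6 in RasV12 cells had 1 probe apart. Its change lay over 2 log2 units from the mean of the others in all 3 pairs, while the others each changed by under 0.5 on average. The third probe of Rrp7a, a ribosomal RNA processing gene, gave -3.54 in p53-null cells and 2.96, -1.24 and -1.34 in the RasV12 pairs, while its other probes gave 0.32 and 0.14 in p53-null cells. For Dnajc19 the bright probe gave -2.67 and -4.14 in p53-null and RasV12 cells and the others, at mean levels of 5.67 and 6.14, lay near background.

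Other assignments of null and heterozygous state within pairs were counted against the real counts. Over both backgrounds the real assignment was the 1 of 32 that called as many as 139 genes, the highest other calling 105 and the next 67. This share is under 0.05 and the smallest that 32 assignments allow. Chance is thus unlikely, though not excluded, as the source of that count in this model. The assignment with 105 flips 1 whole background and so tests the difference between backgrounds. The count of 139 itself was 0 by limma with trended robust eBayes (2407 unadjusted) and 19, 17 or 9 without p53-null pair A, B or C. In p53-null cells the real one was 1 of 4, with 0 as the highest other, and in RasV12 cells 1 of 4, with 121 as the highest other against 786. For the RasV12 effect it was 1 of 10, with 0 as the highest other against 2100. These last designs have too few splits for a share under 0.05.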
